A study of Homo sapiens with 4 samples.

How the data were processed

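MicroRNA levels were measured in SW480 cells, an established human colorectal cancer cell line, on 4 single-colour Agilent human miRNA arrays, 1 for each of 4 groups named in the labels: the parental line, cells grown in suspension (SW480CSCs), suspension cells given a control lentivirus with GFP (SW480CSCs-NC) and suspension cells given a lentivirus with an shRNA against OCT4B1 (SW480CSCs-OCT4B1-shR). They are called the parental, CSC, NC and shR arrays. OCT4B1 is a transcript variant of POU5F1, which a miRNA array does not measure, so the knockdown could not be checked on these arrays. Total RNA was extracted with Trizol, purified with a miRNA isolation kit, dephosphorylated and labelled with Cy3, per the labels' protocols. Scanned images were read with Feature Extraction 11.5.1.1, per the file headers, whereas the submitters' processing notes list Agilent Feature Extraction 10.7. All 4 arrays came from 1 slide and 1 scan, per the file headers.

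Each array held 53144 spots, of which 2164 were control spots, and 50980 belonged to 5893 probes for 2549 human miRNAs, with 20 spots and 1 to 4 probes for each miRNA. The deposited spot values used were background-corrected intensities from Feature Extraction, per the file headers, together with its calls for outlier spots, for spots well above background, for saturation and for detected miRNAs. The authors' deposited value table holds log2 values. Set against each array's own scanner values, they equalled the log2 total gene signal minus 1 constant per array, within 0.001, for all but 4 to 20 of the 2570 features, and the constant lay near the array's log2 90th percentile over all features. In the total gene signal a miRNA that was not detected is listed at 0.1. Why the remaining features departed from the constant stays unknown.

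For each probe, the mean processed intensity over spots that were not outliers was taken, and these means were summed over the probes of a miRNA. Each array was divided by its 75th percentile over the 291 miRNAs detected on all 4 arrays, the scaled signal was rescaled by 1 factor common to all arrays and floored at 1, and the log2 was taken. No spot was saturated. The error given for single miRNAs (spot SE) comes from the spread of the spots on the arrays compared and covers technical error within an array only. With 1 array per group there is no replicate error, no test across samples was possible, and no p-value is given. A miRNA was counted as higher or lower when it was detected on both arrays and differed by at least 2-fold. For a miRNA detected on 1 of 2 arrays the fold is a lower bound, taken against the higher of the lowest detected signal and the miRNA's own signal on the other array. The number of arrays limits the precision.

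Before the data were examined, 3 comparisons were fixed: CSC minus parental, shR minus NC and NC minus CSC. Also fixed were 22 lists of 202 entries, 200 of them on the array, counting repeats between lists, and the rule for the miRNAs named. That rule takes the 10 largest differences in each direction for the first 2 comparisons and 4 for the third, all at least 2-fold with the same direction in every probe and in the total gene signal, up to 3 miRNAs in each direction detected on 1 array, the 10 brightest miRNAs, up to 4 members of each list (the 2 largest differences and the 2 brightest) and up to 6 miRNAs in which the shR array stood apart. Other miRNAs that are named were chosen after their values were seen. The comparisons shR minus CSC and shR minus parental were added after the NC array was seen to stand apart. Beside each list's median stands its percentile among 10000 random lists of the same size matched on signal, as a description of these arrays. The lists are the miR-200 family, let-7, miR-17~92 with its paralogs, embryonic stem cell clusters, p53-induced miRNAs, miR-183, miR-96 and miR-182, miR-15/16, miR-23/27/24, miR-29, miR-30, miR-221 and miR-222, miR-99/100 with miR-125, miR-181, miR-148 and miR-152, colorectal oncomiRs, colorectal tumour suppressors, hypoxia, the 14q32 cluster, the chromosome 19 cluster, stromal markers, blood cell and serum markers, and GC-rich miRNAs that are often bright on arrays and serve as a sign of RNA quality.

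Alternatives were other background correction (normexp with an offset of 50, on median in place of mean spot signals), other summaries (total gene signal, the brightest probe), other scalings (75th percentile over all miRNAs, none, quantile, the median difference set to 0, the authors' values, labelling spike-ins), other filters (detection on all arrays, the brighter 50% of miRNAs, no detection filter, at least 50% of spots well above background), a 1.5-fold threshold and outlier spots kept. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The counting rule was tested on simulated arrays. Both arrays of a simulated pair came from the same real array, with spot noise, the set changes and a common factor added. They held no variation between RNA preparations and no uneven loss like that on the NC array. The counts below thus cover spot noise only and give no rate of false calls for the real comparisons. For CSC minus parental, over 500 miRNAs, it recovered 89 of 95 miRNAs changed by 1.5 log2 units and 105 of 105 changed by 3 units, and counted 5 of 300 without a change. For shR minus NC, over 342 miRNAs, it recovered 87 of 108 and 92 of 92, and counted 2 of 142. In these simulations the scaling moved the median of miRNAs without a change by -0.40 and -0.46. Neighbouring miRNA genes were taken from RefSeq gene positions (assembly GRCh38.p14), in which 373 of the 428 miRNAs detected on the parental, CSC and shR arrays had a gene of the same name, and no coordinates are given because the array files list another build.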

Results

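The arrays asked which miRNAs differ between SW480 cells and the same cells grown in suspension, a culture taken to enrich cancer stem cells, and which differ after a lentiviral shRNA against OCT4B1. Of 2549 miRNAs, 500 were detected on the parental array, 511 on the CSC array, 342 on the NC array and 441 on the shR array. On all 4 arrays 291 were detected, and on at least 1 array 540. Spots well above background numbered 7577 on the parental array, 7643 on the CSC array, 4878 on the NC array and 6757 on the shR array. The summed signal of detected miRNAs was 1184110 units on the parental array, 1346641 on the CSC array, 327905 on the NC array and 1412090 on the shR array. The 2 brightest miRNAs, miR-7975 and miR-7977, held 61.1%, 62.5%, 74.0% and 55.6% of it in the same order. The next brightest by mean signal over the 4 arrays before scaling were miR-5100, the oncogenic miR-21-5p, miR-4284, miR-19b-3p, let-7f-5p, miR-200b-3p, miR-20a-5p and miR-1273g-3p, and 9 of these 10 were also the brightest without the NC array (all but miR-1273g-3p). There were no replicates in any group.

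On the CSC array, miR-1246 was higher than on the parental array by 2.86 log2 units (spot SE 0.04) and miR-1290 by 2.75 (spot SE 0.03), which are 7.27-fold and 6.73-fold. Of the miR-21 hairpin, often raised in cancer, miR-21-3p was higher by 1.23, while miR-21-5p was at 0.91, within 2-fold. Both members of the miR-221 and miR-222 cluster, known to repress the cell cycle inhibitor p27, were higher by 1.01 (miR-221-3p) and 1.05 (miR-222-3p), and miR-222-5p, detected only on the CSC array of this pair, was at least 4.81-fold higher. The values of miR-221-3p and miR-222-3p lay at the 2-fold line, and over all settings miR-222-3p ranged from 0.63 to 1.18. Several GC-rich miRNAs were lower, with miR-6090 at -2.63 (spot SE 0.01) and miR-3665 at -1.73 (spot SE 0.02). Most miRNAs lay close together, with 453 of the 479 detected on both arrays (94.6%) within 2-fold.

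In this comparison 12 miRNAs were at least 2-fold higher and 14 at least 2-fold lower. All 26 differences exceeded 1.96 times their spot SE, which says little, as the median spot SE was 0.05 log2 units. Others higher on the CSC array were miR-133b (1.25), miR-584-5p (1.24), miR-133a-3p (1.21), miR-1-3p (1.15), miR-22-5p (1.04) and miR-1273f (1.02), of which miR-1, miR-133a and miR-133b are best known from muscle. Others lower were miR-6821-5p (-2.42), miR-4739 (-1.74), miR-134-5p (-1.35), miR-3960 (-1.31), miR-6728-5p (-1.23), miR-4763-3p (-1.23), miR-1207-5p (-1.16) and miR-4281 (-1.15). Of 53 miRNAs detected on 1 of the 2 arrays, 32 were on the CSC array and 21 on the parental array. Lower bounds were 4.30-fold for miR-7845-5p and 1.81-fold for miR-3138 in favour of the CSC array, and 3.80-fold for miR-3188, 2.86-fold for miR-1247-3p and 2.56-fold for miR-4734 in favour of the parental array. No replicate checks these differences. With normexp background correction of median spot signals 2 were higher and 5 lower, and with the authors' values 27 were higher and 18 lower.

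**Figure D1:**
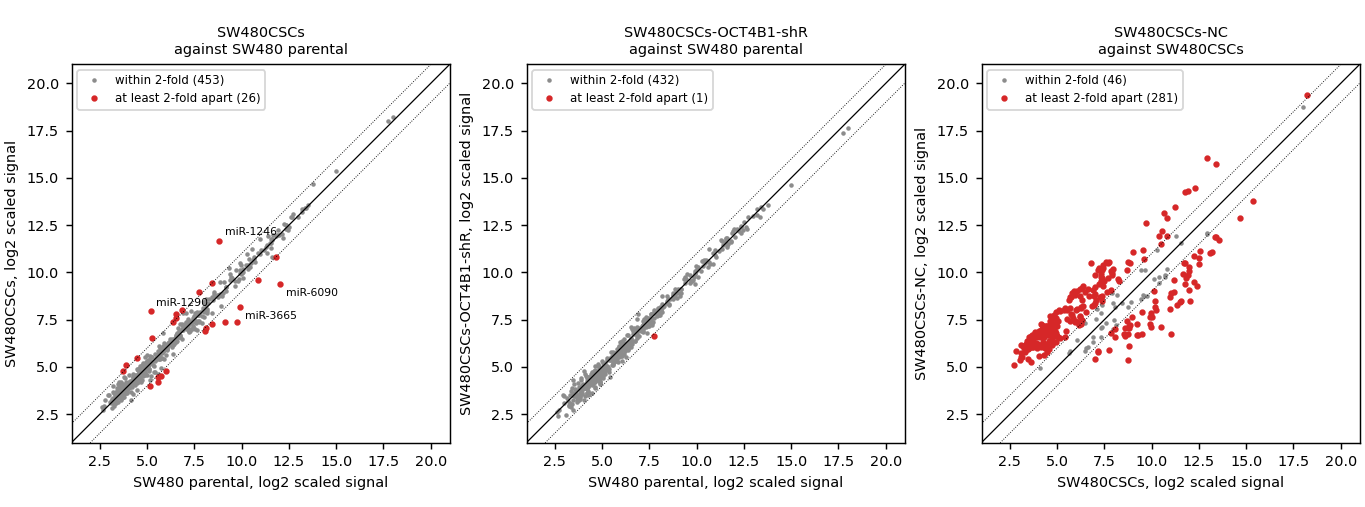
Log2 scaled signal of each miRNA detected on both arrays (1 array per group), for SW480CSCs against SW480 parental, SW480CSCs-OCT4B1-shR against SW480 parental and SW480CSCs-NC against SW480CSCs. The solid line marks equal signal, dotted lines mark 2-fold, and red points are at least 2-fold apart: 26 in the first panel, 1 in the second and 281 in the third.

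The lists fixed beforehand were mostly close to 0 in CSC minus parental, where the median of all miRNAs was 0.03. All 9 members of the miR-200 family were detected on both arrays and within 2-fold, with a median of 0.01 (percentile 22.8), as were the 9 members of the let-7 family with a median of 0.08 (percentile 48.0). The 12 detected members of miR-17~92 and its paralogs were all within 2-fold and all above the median of all miRNAs, with a median of 0.18 (percentile 86.8), led by miR-18a-5p at 0.62 and miR-18b-5p at 0.49. Of the 11 colorectal oncomiRs 10 were above the median of all miRNAs, with a list median of 0.19 (percentile 89.9), and they included miR-31-5p at 0.50 and miR-135b-5p at 0.43. That list shares miR-17-5p, miR-20a-5p and miR-92a-3p with the one before. Both strands of the hypoxia-induced miR-210 were above 0, miR-210-3p at 0.68 and miR-210-5p at 0.77 (percentile 99.8). They come from the same hairpin, while the percentile counts them as independent members, and miR-210-5p was not detected on the NC and shR arrays. The miR-221 and miR-222 cluster had a median of 1.03 (percentile 95.6). The miR-29 family had a median of 0.31 (percentile 89.2) and miR-23/27/24 one of 0.15 (percentile 56.7). Medians were -0.04 for the p53-induced miRNAs (percentile 12.6), -0.05 for miR-30 (percentile 23.0), -0.05 for miR-181 (percentile 20.5), -0.08 for miR-99/100 with miR-125 (percentile 19.2) and -0.15 for miR-148 and miR-152 (percentile 13.9). They were 0.06 for miR-183, miR-96 and miR-182 (percentile 54.3) and 0.08 for miR-15/16 (percentile 62.7).

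Of the 8 detected colorectal tumour suppressor miRNAs, 1 was at least 2-fold higher, miR-133a-3p, and the median was -0.09 (percentile 9.75), with miR-375 at -0.57. Of the 12 miRNAs in the embryonic stem cell clusters only miR-371b-5p was detected, at -0.69 (percentile 9.66), and none of the 17 chromosome 19 cluster miRNAs on the array was detected on these 2 arrays. From the 14q32 cluster 2 of 30 were detected, miR-134-5p at -1.35 and miR-494-3p at 0.80 (median percentile 15.8). The 4 detected stromal markers had a median of 0.18 (percentile 85.2), with miR-10b-5p at -0.35 and miR-126-3p at 0.21. The 5 detected blood and serum markers had a median of 0.19 (percentile 78.2), with miR-451a at 0.71. The GC-rich list, a sign of RNA quality, had a median of -0.30, below all 10000 random lists, and 7 of its 20 members were at least 2-fold lower. Without that list 12 miRNAs were higher and 7 lower. No sequences were used, so the 7 may include other GC-rich miRNAs.

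The comparison of the shR with the NC array asks about the shRNA against its vector control. Among the 10 largest differences in favour of the shR array, 3 were in miRNAs of the miR-200 family and 3 in p53-induced miRNAs. Against the NC array miR-200a-3p was higher by 3.81 log2 units, miR-141-3p by 3.38 and miR-429 by 3.13, all of the miR-200 family, which maintains epithelial identity, and miR-194-5p by 3.47, miR-192-5p by 3.26 and miR-215-5p by 3.09, which p53 is known to induce. Of the 6 miR-200 family members detected on both arrays, 4 were at least 2-fold higher. Within 2-fold were miR-200b-5p (0.64) and miR-200c-3p (0.19), which were at 3.93 and 3.48 without scaling. All 6 lay above the median of all miRNAs detected on both arrays, by unequal amounts. Another 3 members were detected on the shR array and not on the NC array. The largest difference was that of the heart and muscle miRNA miR-499a-5p, at 4.93 (spot SE 0.13), and also higher were miR-26b-5p by 3.55, miR-30e-5p by 3.46 and miR-148a-3p by 3.17. All 10 were higher under each of the scalings tried, from 3.81 to 7.37 for miR-200a-3p. Over all settings that gave a value 9 of them stayed at least 2-fold higher, while miR-30e-5p fell to 0.46. These differences lay mostly on the NC array, since shR minus CSC was 0.27 for miR-200a-3p and 0.62 for miR-499a-5p.

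Of 295 miRNAs detected on both arrays, 63 were at least 2-fold higher and 178 at least 2-fold lower on the shR array. All 241 differences exceeded 1.96 times their spot SE, which says little, as the median spot SE was 0.06 log2 units. Scaling decided the split between higher and lower. The 75th percentile was 1564 units on the shR array and 160 on the NC array, so that the median difference of all miRNAs was 1.58 before scaling and -1.71 after it. Before scaling 184 were higher and 1 lower, against the labelling spike-ins 211 and 0, with quantile normalization 78 and 134, with the median difference set to 0 105 and 80, with the authors' values 94 and 121, and with the 75th percentile over all miRNAs 119 and 40. The lowest scaled values were those of miR-4430 (-4.32), miR-1273g-3p (-3.75), miR-663b (-3.74), miR-6132 (-3.63) and miR-6813-3p (-3.57), for which differences without scaling were -1.03, -0.46, -0.45, -0.34 and -0.28. Next were miR-6737-3p (-3.48), miR-3180-5p (-3.45), miR-4299 (-3.45), miR-197-5p (-3.42) and miR-4649-3p (-3.38), which were above 0 by 0.08 to 0.18 against the spike-ins. Detected on the shR array and not on the NC array were 146 miRNAs, and 47 the other way round. Lower bounds, which rest on the same scaling, were 23.1-fold for miR-146a-5p, 10.9-fold for miR-375 and 9.57-fold for miR-135b-5p in favour of the shR array. For the NC array they were 26.6-fold for miR-4521, 19.4-fold for miR-6759-3p and 15.7-fold for miR-933.

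Relative to the median of all miRNAs detected on both arrays, which no single factor per array can move, the lists separated in shR minus NC. That median covers 295 miRNAs and leaves out 146 detected on the shR array alone. A list far above it can still be ordinary for its signal, as was let-7 at percentile 56.8. The percentiles, which are matched on signal, are therefore the closer measure. The p53-induced list lay 4.88 log2 units above that median (4 members, percentile 99.4), the miR-200 family 4.41 (6 members, percentile 99.98), the miR-30 family 4.32 (3 members, percentile 97.7) and the blood and serum markers 4.13 (3 members, percentile 99.6). Further lists lay above it by 3.78 for miR-23/27/24 (percentile 94.7), 3.32 for miR-15/16 (percentile 86.7), 3.12 for miR-29 (percentile 71.5), 2.95 for the oncomiRs (percentile 91.0), 2.84 for miR-17~92 and paralogs (percentile 74.0), 2.62 for let-7 (percentile 56.8), 2.13 for miR-181 (percentile 83.3) and 1.23 for miR-221 and miR-222 (percentile 72.1). The tumour suppressor list lay 3.51 above it with 2 members. Lists with 1 member were miR-148 and miR-152 at 4.88, miR-183, miR-96 and miR-182 at 4.58, hypoxia at 3.61 and the stromal markers at 2.87. Close to the median were miR-99/100 with miR-125, 0.63 above (4 members, percentile 45.7), the GC-rich list, 0.30 above (20 members, percentile 37.8) and the embryonic list with its 1 member, 0.05 below. The 14q32 list, with miR-494-3p alone, lay 1.64 below, and no chromosome 19 cluster miRNA was detected on both arrays.

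By their labels, the NC and CSC arrays differ by the control lentivirus. Before scaling, miRNA families were dimmer on the NC array. The miR-200 family had a median difference of -5.38 log2 units (percentile 0.04), while that of the GC-rich list was -1.21 (percentile 87.2). Medians without scaling were -5.69 for the p53-induced list (percentile 1.35), -4.88 for miR-23/27/24 (percentile 6.22) and -4.35 for miR-17~92 and paralogs (percentile 9.6). They were -3.64 for let-7 (percentile 48.9) and -1.62 for miR-99/100 with miR-125 (percentile 49.9). These last lists were ordinary for their signal, so not every family was dimmer than other miRNAs of like signal. Members within a family differed too, as in let-7, where let-7g-5p was at -4.46 and let-7b-5p at -2.17. In the miR-200 family miR-141-3p was at -5.92 and miR-200c-3p at -2.76. The median of all miRNAs was -0.998 without scaling and 1.79 with it. With scaling 216 of 327 miRNAs were at least 2-fold higher on the NC array and 65 lower, without it 0 and 163, against the spike-ins 0 and 158, and with the 75th percentile over all miRNAs 52 and 105. With scaling, the highest on the NC array were miR-4430 (3.72), miR-6512-5p (3.14), miR-1273g-3p (3.12) and miR-933 (3.10), which were at 0.32 to 0.93 without scaling, and the lowest were miR-499a-5p (-4.30), miR-200a-3p (-3.54), miR-26b-5p (-3.37) and miR-30e-5p (-3.37). The labelling spike-ins were at about the same signal on both arrays, 430 units against 470 for dmr_285 and 170.2 against 167.6 for dmr_31a, and the Feature Extraction metric for them was out of range on the NC and shR arrays.

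**Figure D2:**
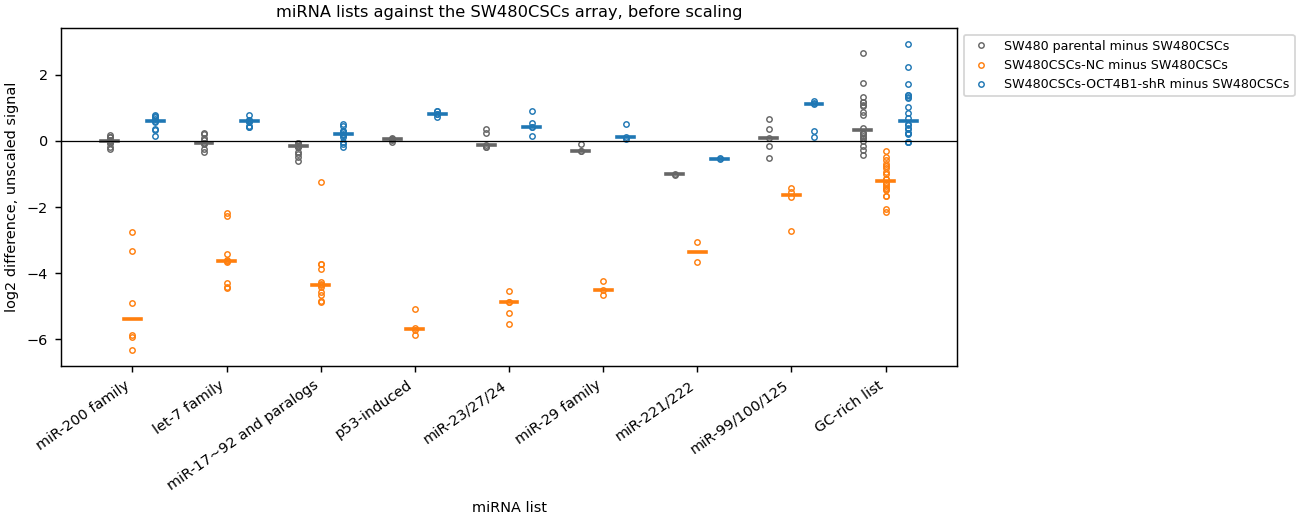
Log2 difference of signal before scaling from the SW480CSCs array, for members of 9 miRNA lists detected on both arrays (circles) and their median (bars), on the SW480 parental, SW480CSCs-NC and SW480CSCs-OCT4B1-shR arrays (1 array each). On the SW480CSCs-NC array the miR-200 family has a median of -5.38 and the GC-rich list one of -1.21.

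Among the 3 suspension-culture arrays, 291 miRNAs were detected on all 3, and the NC array stood apart most often. It was at least 2-fold higher than both others in 168 and lower than both in 58, against 3 and 2 for the CSC array and 3 and 8 for the shR array. Without scaling the NC array had 0 higher and 159 lower, and the shR array 23 higher and 0 lower. The shR array's scaled signal was lower than both others in miR-1290, miR-1246, miR-193b-3p, miR-1268a and miR-663b, none of which passed this rule without scaling, and higher in miR-6090. Against the CSC array these differences were -3.10, -2.93, -1.46, -1.21, -1.17 and 2.44.

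Because the NC array stood apart, the shR array was also set against the CSC and parental arrays. Against the CSC array, miR-1290 (-3.10) and miR-1246 (-2.93), both higher on the CSC than on the parental array, were lower on the shR array. So were miR-21-3p (-2.34), miR-21-5p (-1.13), miR-221-3p (-1.05) and miR-222-3p (-1.03). Without scaling miR-21-3p was at -1.83, while miR-21-5p (-0.62), miR-221-3p (-0.54) and miR-222-3p (-0.52) were within 2-fold, and with quantile normalization miR-21-5p was at 0.00. Higher on the shR array were miR-6090 (2.44), miR-6821-5p (2.17), miR-3665 (1.74), miR-4739 (1.38) and miR-4281 (1.21), of which miR-6090, miR-3665 and miR-4281 are on the GC-rich list, a sign of RNA quality, and 2 remained without that list. Of 434 miRNAs 5 were at least 2-fold higher and 14 lower, while without scaling, where the median of all miRNAs was 0.39 in place of -0.12, 31 were higher and 3 lower, and against the spike-ins 95 and 3. Against the parental array 432 of 433 miRNAs detected on both lay within 2-fold, with miR-21-3p lower (-1.11), while against the spike-ins 69 were higher and 0 lower. A further 67 were detected on the parental array alone and 8 on the shR array alone. Negative controls spread more on the shR array, with an SD of 11.4 units against 3.0 to 3.7 on the others.

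Scaled signals across the 291 miRNAs correlated at r = 0.996 between the parental and shR arrays, 0.985 between parental and CSC and 0.983 between CSC and shR, and at 0.738 to 0.763 between the NC array and the others. These are correlations across miRNAs, which are not independent replicates. Of 428 miRNAs detected on the parental, CSC and shR arrays, the CSC array was at least 2-fold higher than both others in 7 (miR-1246, miR-1290, miR-193b-3p, miR-21-3p, miR-221-3p, miR-222-3p and miR-584-5p) and lower in 5 (miR-3665, miR-4281, miR-4739, miR-6090 and miR-6821-5p), against 0 and 0 for the parental array and 0 and 1 for the shR array. Without scaling 3 of the 7 (miR-1246, miR-1290 and miR-21-3p) and all of the 5 passed this rule, of 3 higher and 14 lower in all, and with normexp 2 of the 7 and 4 of the 5. Both differences of this kind use the same CSC array, so its own error enters each.

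**Figure D3:**
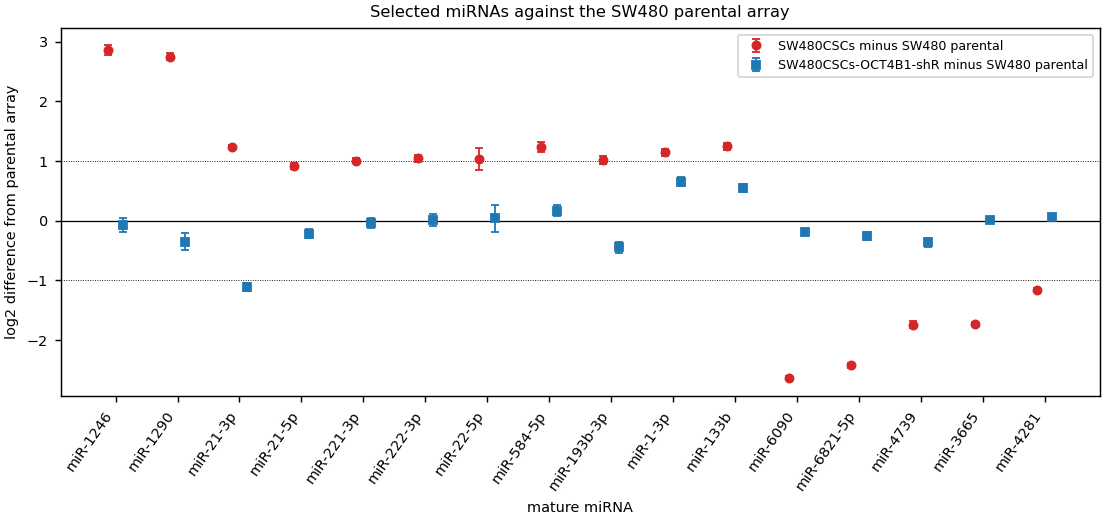
Log2 difference in scaled signal from the SW480 parental array for 16 miRNAs, on the SW480CSCs array (circles) and the SW480CSCs-OCT4B1-shR array (squares), 1 array each. Bars show 1.96 times the spot SE, which covers technical error within arrays only, and dotted lines mark 2-fold. On the SW480CSCs array miR-1246 is at 2.86 and miR-6090 at -2.63, and on the SW480CSCs-OCT4B1-shR array miR-21-3p is the miRNA beyond 2-fold, at -1.11.

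The 2 differences that share no array, CSC minus parental and shR minus NC, had a Pearson r of -0.05 and a Spearman rho of 0.01 across the 291 miRNAs. With the main scaling, of 7 higher on the CSC array, 4 were lower on the shR array, against 4.19 for independent lists, and of 10 lower on the CSC array 3 were higher on the shR array, against 2.16. In the same direction 0 were higher in both, against 1.52, and 1 was lower in both, against 5.98. These overlaps depend on the scaling of the NC array. Without scaling, of 6 higher on the CSC array 5 were higher and 0 lower on the shR array, against 3.79 and 0.02, and of 10 lower on the CSC array 10 were higher and 0 lower, against 6.32 and 0.03.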

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

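Of the alternatives, normexp on median spot signals, scaling to the labelling spike-ins and the counts without the GC-rich list were chosen after seeing the data, as were the comparisons shR minus CSC and shR minus parental and the counts among the parental, CSC and shR arrays, and the cause of changes between settings was not tested. No paired analysis was possible because each group had 1 array. The planned normexp on mean spot signals was not run, as that column was not in the files used, nor was the slide as a block, as all arrays came from 1 slide. Low signal over background limited the NC array most. Of the 20 miRNAs named by size in CSC minus parental, 7 stayed at least 2-fold apart in every setting that gave a value, and 9 of 20 in shR minus NC. Over all settings, 1055 list medians stayed within 1.96 times their SE (over members, or over spots for 1 member), 487 moved and 26 that were at least 2-fold from 0 changed sign, and of differences of named miRNAs 480, 442 and 5. Whatever their size, 155 of 1568 list medians changed sign, among them 22 of 105 without scaling, 23 against the spike-ins and 17 with the 75th percentile over all miRNAs. Counts follow as higher and lower, with the main values first.

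Main counts were 12 and 14 for CSC minus parental, 63 and 178 for shR minus NC, 216 and 65 for NC minus CSC, 5 and 14 for shR minus CSC, and 0 and 1 for shR minus parental. Among the suspension arrays the main counts standing apart were 3 and 2 (CSC), 168 and 58 (NC), and 3 and 8 (shR). Among the parental, CSC and shR arrays the CSC array's main counts were 7 and 5, and they were 3 and 14 without scaling, 3 and 14 against the spike-ins, 4 and 14 with the 75th percentile over all miRNAs, 4 and 8 with quantile normalization, 5 and 8 with the median difference set to 0, 9 and 11 with the authors' values, 2 and 4 with normexp, 40 and 28 with no detection filter, 4 and 5 with detection by spots well above background, and 25 and 17 at 1.5-fold.

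Without scaling they were 184 and 1 for shR minus NC, 0 and 163 for NC minus CSC, 31 and 3 for shR minus CSC, and 11 and 0 for shR minus parental, with 0 lower on the CSC array, 0 and 159 apart for NC, and 23 and 0 for shR. List medians at least 2-fold from 0 that changed sign were 1.54 (embryonic clusters), 2.21 (miR-99/100 with miR-125) and 1.88 (GC-rich) in shR minus NC, and -1.28, -1.62 and -1.21 in NC minus CSC, with -0.29 for 14q32.

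Against the spike-ins they were 211 and 0 for shR minus NC, 0 and 158 for NC minus CSC, 95 and 3 for shR minus CSC, and 69 and 0 for shR minus parental, with 0 lower for CSC, 0 and 156 for NC, and 59 and 0 for shR. List medians at least 2-fold from 0 that changed sign were 1.80 (embryonic), 2.48 (miR-99/100 with miR-125), 0.21 (14q32) and 2.15 (GC-rich) in shR minus NC, and -1.23, -1.57, -0.24 and -1.16 in NC minus CSC. In shR minus NC miR-6737-3p was at 0.078, miR-3180-5p at 0.11, miR-4299 at 0.11, miR-197-5p at 0.13 and miR-4649-3p at 0.18.

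With the 75th percentile over all miRNAs they were 119 and 40 for shR minus NC, 52 and 105 for NC minus CSC, 16 and 4 for shR minus CSC, and 3 and 0 for shR minus parental, with 0 lower for CSC, 30 and 101 for NC, and 9 and 0 for shR. List medians at least 2-fold from 0 that changed sign were 0.32 (embryonic), 0.99 (miR-99/100 with miR-125) and 0.66 (GC-rich) in shR minus NC, and -0.28, -0.62 and -0.21 in NC minus CSC.

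With the median difference set to 0 they were 105 and 80 for shR minus NC, 83 and 98 for NC minus CSC, 8 and 9 for shR minus CSC, and 1 and 0 for shR minus parental, with 0 lower for CSC, 51 and 92 for NC, and 6 and 2 for shR. The miR-99/100 with miR-125 median was 0.53 and the GC-rich median 0.19 in shR minus NC, and the former -0.34 in NC minus CSC.

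With quantile normalization shR minus CSC had 9 and 6, and the shR array 5 lower. With the authors' values CSC minus parental had 27 higher, NC minus CSC 139 higher, shR minus CSC 16 higher and shR minus parental 5 and 8, with 103 higher for NC and 5 higher for shR, and the miR-99/100 with miR-125 median was 0.043 in shR minus NC.

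With normexp on median signals CSC minus parental had 2 and 5, NC minus CSC 42 lower, shR minus CSC 5 lower and shR minus parental 0 lower, with 38 lower for NC and 1 and 3 for shR, and the stromal median was -0.72 in shR minus NC. With the total gene signal shR minus CSC had 27 lower and shR minus parental 2 and 16, with 5 higher for CSC and 16 lower for shR. With the brightest probe shR minus parental had 2 lower, and the CSC array 6 higher.

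With detection on all 4 arrays CSC minus parental had 7 higher. In the brighter 50% of miRNAs shR minus NC had 110 lower and NC minus CSC 116 higher, with 105 higher for NC. With no detection filter they were 66 and 81 for CSC minus parental, 213 and 798 for shR minus NC, 798 and 212 for NC minus CSC, 81 and 102 for shR minus CSC, and 70 and 102 for shR minus parental, with 30 and 47 for CSC, 767 and 174 for NC, and 30 and 69 for shR. With detection by spots well above background CSC minus parental had 7 higher and shR minus parental 2 lower, 52 miRNAs were detected on 1 of the arrays in shR minus CSC (84 in the main setting) and 41 in shR minus parental (75), with 4 lower for CSC and 1 higher for shR.

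At 1.5-fold they were 31 and 27 for CSC minus parental, 25 and 49 for shR minus CSC, and 7 and 21 for shR minus parental, with 10 and 13 for CSC, and 7 and 28 for shR. Without the GC-rich list CSC minus parental had 7 lower and shR minus CSC 2 higher.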

Other observations

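The re-pairing tests of hairpin arms and of neighbouring genes over all pairs were set before their results were seen, and the other tests in this part, with the re-pairings that leave out 1 pair, were chosen after the values they rest on were seen.

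Some miRNAs known mainly from other tissues were well detected in these colorectal cells. The blood cell miRNA miR-142-3p had a log2 scaled signal of 11.32 on the parental array, with 0.15 for CSC minus parental and -0.23 for shR minus CSC, and miR-146a-5p had 9.51 on the parental array. The myeloid and red cell miRNAs miR-223-3p and miR-451a were at 3.19 and 3.51 on that array, and miR-223-3p was not called detected there. The heart and muscle miRNA miR-499a-5p was at 11.34. Lists with a percentile under 5 or over 95 were, relative to the median of all miRNAs in shR minus parental, the blood and serum markers at 0.51 (5 members, percentile 99.98), the stromal markers at 0.42 (4 members, percentile 99.2), the p53-induced list at 0.39 (5 members, percentile 99.7), the colorectal tumour suppressors at 0.27 (8 members, percentile 99.5), the GC-rich list at -0.17 (20 members, percentile 0.09) and the embryonic list's 1 member at -0.86 (percentile 1.02). In shR minus CSC they were miR-99/100 with miR-125 at 0.74 (5 members, percentile 99.9), the p53-induced list at 0.43 (5 members, percentile 98.0), the tumour suppressors at 0.42 (8 members, percentile 99.4), miR-181 at 0.34 (4 members, percentile 96.2), miR-17~92 and its paralogs at -0.18 (12 members, percentile 4.33), and miR-221 and miR-222 at -0.92 (percentile 2.30). Beside these, the GC-rich list, a sign of RNA quality, was at 0.21 in shR minus CSC (20 members, percentile 96.7). Some of these lists overlap. Of detected members, the tumour suppressors share miR-126-3p and miR-133a-3p with the stromal markers and miR-34a-5p with the p53-induced list.

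The NC array was dim for miRNA families. Over 57 members of 13 family lists, picked from the 22 lists after their values were seen, detected on the CSC and NC arrays, the median difference without scaling was -4.36, from -6.33 to -1.25. Less labelled RNA of every kind, as the only cause, would lower the GC-rich list as much, but that list lay 3.16 log2 units above the families. The GC-rich list and the families were not matched on signal, and that list is itself a sign of RNA quality. So this test cannot exclude less labelled RNA alongside another cause. An equal loss of all mature miRNAs would move the members by 1 factor, but their interquartile range was 3.32 times that of shR minus CSC over the same members, with a median spot SE of 0.03. Lentiviral transduction as such would lower the families on the shR array too, where, if its label is right, the median against the CSC array was 0.53 without scaling. Less labelled RNA alongside another cause, an uneven loss of miRNAs in this RNA preparation, for example by base composition, and an effect of the control vector may each remain. With 1 array and no sequences used here, none of these was tested.

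The CSC array stood apart from the parental and shR arrays, with 25 of 428 miRNAs at least 2-fold apart in CSC minus parental against 1 in shR minus parental, but with 24 against 10 without scaling, 33 against 18 with the total gene signal, 36 against 13 with the authors' values and 23 against 66 with scaling to the spike-ins. Noise of single miRNAs would leave the arms of a hairpin unrelated, but over 57 pairs of 5p and 3p arms the CSC array's deviations from the mean of the other 2 arrays correlated at r = 0.59 (rho 0.34, same sign in 34 pairs), above the highest of 10000 re-pairings matched on signal (0.485). This rests in part on the miR-21 hairpin, without which r was 0.478 and rho 0.30. These were no longer above every re-pairing, as 3 of 10000 re-pairings without that hairpin reached that r and 73 that rho. The next largest deviations, those of miR-22 (1.02 and 0.77) and miR-221 (0.91 and 1.03), stayed in. Whether the remaining hairpins deviate together without them was not tested, so the result may rest on few hairpins. Of the 12 miRNAs that set the CSC array apart, only miR-21-3p and miR-221-3p are in these arm pairs. The test says nothing about noise in the others, among them miR-1246, miR-1290 and miR-6090. Variation between arrays that moves related miRNAs together, a difference in the culture or RNA of this 1 preparation, a wrong label and a biological difference between suspension cells with and without the shRNA may each remain, and were not tested, as the array does not measure OCT4B1. The GC-rich list moved with this pattern, with 5 of the 12 miRNAs that set the CSC array apart being lower and 3 of those 5 on the list. Whether the others of the 5 are GC-rich was not checked, as no sequences were used.

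A hypothesis was that miRNAs of neighbouring genes deviate together on the CSC array, as they would if the differences arose at transcription. Over 112 pairs whose genes lay within 10 kb, leaving out arms of the same hairpin and copies with the same number, the deviations correlated at r = 0.45 (rho 0.27, same sign in 69 pairs), against at most 0.33 in 10000 re-pairings. Without the pair of miR-221-3p and miR-222-3p r was 0.395 and rho 0.25, and of 10000 re-pairings without it 0 reached that r and 27 that rho. The pair of miR-221-5p and miR-222-3p from the same locus stayed in, so this does not show that r is independent of that locus. The hypothesis passed this test, but pairs share members, while the re-pairings drew a value for each pair independently, so their range may be too narrow. Cross-hybridisation among similar sequences in a cluster may also add to r, which was not tested.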
